A study of Mus musculus with 27 samples.

How the data were processed

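Ventricle tissue of mice was profiled by RNA sequencing in 27 libraries. Per the labels' protocols, total RNA was isolated with TRIzol and a column kit, and BGI built and ran the libraries on its DNBseq platform. The labels give the tissue, the age, the MBNL1 genotype class and, for the animals at postnatal day 60, the days after knockout. The way the knockout was induced, the part of the gene deleted, the promoter of the transgene and the sex of the animals were not given in the sources used here. The labels do not state that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. Counts of Xist and Y-linked genes gave both sexes in every group, so no group came from a single animal. How many animals each group held is not known here.

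The deposited table held counts, whole numbers of reads per gene and library, with totals that differed between libraries. STAR, featureCounts, DESeq2, Salmon and the mouse genome build GRCm38 (mm10) are named per the submitters' processing notes, which give no role, order or version. The annotation release, the strand setting and any filter were not given in the sources used here. The table covered 55487 Ensembl genes, of which 35145 had at least 1 count in some library. Symbols and coordinates came from GENCODE M21 on GRCm38, which held 55141 of the gene identifiers and lacked 346. Genes without a symbol were tested but are not named, and their share of the counts was not measured. Reads of near-identical copies, among them the mitochondrially encoded genes and their nuclear copies, the globins, the tubulins and the ribosomal proteins, may have been split between genes in the authors' counting, so their values are uncertain, and without a stated strand setting a gene cannot be told apart from an overlapping antisense partner.

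Total counts ran from 21929347 to 25675115 per library. In the smallest library, 3 counts, the limit that a count of 0 allows, equal 0.137 CPM before the TMM scaling described below. Such floors cover counting error only. After TMM scaling the floor is higher in the day 60 controls, where 3 counts in 7-day control library 2 equal 0.166 CPM. Pairs of libraries within a group were compared by a chi-square test over genes with at least 20 summed counts. The statistic per degree of freedom ran from 6.34 to 147 over the 40 pairs, so no pair agreed within sampling noise and each library was counted as 1 sample.

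Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with few counts were removed with filterByExpr, library sizes were scaled by TMM, and differences were tested with the quasi-likelihood F test (glmQLFit and glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Levels are counts-per-million values (CPM) after TMM scaling over all 27 libraries, given as mean ± SD. Log2 fold changes are given ± SE, calculated back from the test as the absolute log2 fold change over the square root of its F statistic. The libraries labelled KO at 7 and at 14 days were each compared with the controls that carry the same time, in fits of those groups only. A fit of the 16 libraries of postnatal day 60 tested whether the response differed between the times. The transgenic libraries were compared with the controls of postnatal day 7. Control ages were compared in a fit of the 14 control libraries, with both control groups of postnatal day 60 averaged. The fits at 7 days, at 14 days and for the transgene shared no library.

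A total of 41 gene lists with 930 entries was fixed before the data were examined, as were the tests, the samples in each fit, the alternative settings and the rule for genes named in the text. The lists cover contractile, metabolic, cell cycle, stress, splicing and matrix genes and markers of the other cell types of the ventricle. Each was tested with camera from limma 3.58.1 on voom values with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. The test was repeated with an estimated correlation and with fry. Called members were counted after adjustment over all genes tested and again adjusted over the list alone. Maturation gene sets were taken from control libraries outside the comparison they were tested in, as genes called and at least 2-fold different between postnatal days 60 and 1. For the comparison at 7 days the sets used the day 60 controls of 14 days, for the comparison at 14 days those of 7 days, and for the transgene both. Overlaps of calls were set beside the number that independent lists give. The share of counts from mitochondrially encoded genes was compared with two-sided exact permutation tests.

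The named genes are Mbnl1, Mbnl2 and Mbnl3 in every comparison. They include the 8 genes with the largest rise and the 8 with the largest fall among those called, with a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a model or clone name, leaving out Xist and Y-linked genes. For the difference between the times and for the check of the day 60 controls, 5 genes each way were taken. Up to 4 called members with the largest change were taken from each list with at least 3 called members or an adjusted list p under 0.05. A gene named outside this rule is said to have been chosen after its values were seen.

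The alternatives were DESeq2 1.42.0 size factors and the DESeq2 test, limma-voom, total count scaling, no filter or a filter at 1 CPM, a threshold of 2-fold, all 27 libraries in a single fit, a term for sex read from expression, 1 surrogate variable from sva 3.50.0, a block for the replicate number, the mitochondrially encoded genes left out, each day 60 control group alone, sets at 4-fold, and each library left out in turn. The fits with a block for the replicate number kept only libraries whose number occurs in both groups compared. Leaving out a pair of libraries labelled KO at 7 days, or a pair of controls of postnatal day 1, was added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

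The tests were tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed. Of genes changed 2-fold, 63.6% were recovered in the simulated comparison at 7 days, 73.2% at 14 days, 81.9% for the transgene, 80.0% for postnatal day 7 against day 1, 71.7% for day 60 against day 7, 75.4% for day 60 against day 1 and 71.7% for the day 60 controls. For the difference between the times, 38.5% of genes changed 2-fold and 86.8% of genes changed 4-fold were recovered. False calls made up from 3.76% of the simulated calls for the day 60 controls to 7.88% for day 7 against day 1. Simulated genes varied independently, and most real comparisons called far more genes, 7693 at 7 days. These rates may therefore not hold for the real data.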

Results

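Gene expression was measured by RNA sequencing in ventricles of mice in 27 libraries of 7 groups, to describe normal postnatal expression and the effects of changing the dose of MBNL1, an RNA-binding protein that regulates splicing and RNA stability. At postnatal day 60 there were 5 libraries labelled KO (loss of function) and 4 controls at 7 days after knockout, and 4 libraries labelled KO and 3 controls at 14 days. At postnatal day 7 there were 4 libraries labelled Tg (gain of function) and 3 controls, and at postnatal day 1 there were 4 controls. Total counts ran from 21929347 to 25675115 per library. The first principal component, with 48.5% of the variance over 17261 genes, placed the day 60 libraries between -73.5 and -39.5, those of day 7 between 61.5 and 82.6 and those of day 1 between 79.4 and 106. The second component, with 20.9%, placed the 9 libraries labelled KO between 30.3 and 87.4 and the 7 controls of day 60 between -62.5 and -55.1. Libraries 1 and 5 labelled KO at 7 days stood apart on the fourth component (4.47%), at -52.1 and -56.9 against -2.13 to 19.6 in the other 3. Of the day 1 controls, libraries 3 and 4 lay at 79.4 and 90.7 on the first component, against 106 and 105 in the others.

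**Figure D1:**
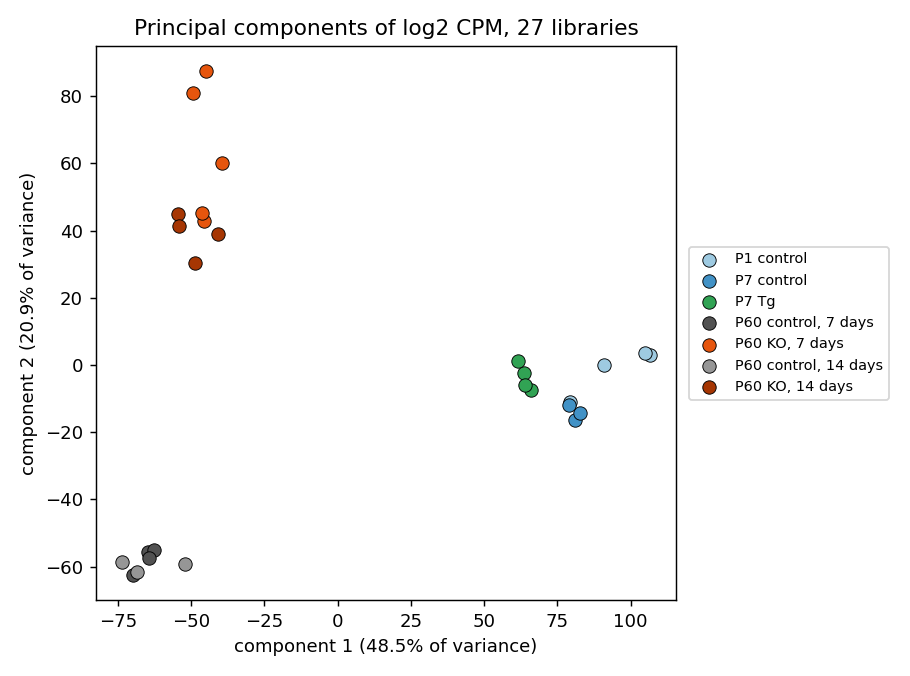
Scores of the 27 libraries on the first principal components of log2 CPM (horizontal and vertical axes in component units), with each point a library coloured by group. The libraries labelled KO lie between 30.3 and 87.4 on the second component and the day 60 controls between -62.5 and -55.1.

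Mbnl1 (ENSMUSG00000027763, chromosome 3, 60472830 to 60629750 on the plus strand of GRCm38) was examined first in every library, since it checks the labels. At 7 days the libraries labelled KO held 219, 103, 168, 116 and 166 CPM of Mbnl1, against 152, 145, 149 and 147 in their controls. At 14 days they held 139, 137, 117 and 123 CPM, against 169, 158 and 152. The log2 fold change was 0.05 ± 0.20 at 7 days (adjusted p = 0.86, edgeR quasi-likelihood with Benjamini-Hochberg adjustment) and -0.34 ± 0.09 at 14 days (adjusted p = 0.012). The fall at 14 days was not called without control library 5 (-0.30), with all 27 libraries in a single fit or with replicate number as a block (2 libraries per group), and turned to 0.03 with total count scaling. The gene total was thus not lower on average at 7 days, where libraries 2 and 4 labelled KO lay below all 4 controls and libraries 1, 3 and 5 above them. Over the 9 libraries labelled KO, Mbnl1 was lower where Esr1 was higher (Pearson r = -0.877, exact permutation p = 0.0031, and rho = -0.70, p = 0.043), a relation examined after the values were seen. The permutation exchanged libraries between the times, and all libraries of 14 days had high Esr1 (1672 to 1983 CPM). These p-values thus do not measure a relation within a time. With each library left out, r ran from -0.927 to -0.862 with p under 0.05. The p of rho was 0.05 or more without 7 of the 9 libraries, 0.115 without library 1, 2 or 3, 0.096 without library 5 and 0.058 without library 6, 7 or 8. The deleted part of the gene is not known here, and these libraries are called by their label throughout. The paralog Mbnl2 (ENSMUSG00000022139, chromosome 14) had a log2 fold change of -0.34 ± 0.14 at 7 days (adjusted p = 0.073), which turned to 0.08 with total count scaling and was called without KO library 3. At 14 days it changed by -0.64 ± 0.12. Mbnl3 (ENSMUSG00000036109, chromosome X) stood at 1.22 CPM against 0.233 at 7 days, where the rise was called (adjusted p = 0.0012, edgeR quasi-likelihood). Mbnl3 had only 8, 3, 3 and 2 counts in those controls, near the floor of 3 counts. At 14 days it stood at 0.801 against 0.322 (adjusted p = 0.057), and the rise was called without KO library 8 (1.55) and with all 27 libraries in a single fit (1.29). It was also called with total count scaling, no low-count filter, a sex covariate, a surrogate variable or replicate number as a block.

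Of all genes tested, Esr1 had the largest log2 fold change at 14 days, 10.75 ± 0.16 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614 on the plus strand of GRCm38). It encodes the estrogen receptor alpha. The libraries labelled KO at 7 days held 234, 1905, 651, 1671 and 193 CPM of Esr1 and those at 14 days 1721, 1882, 1983 and 1672, while the day 60 controls held 0.482 to 1.49. In the libraries labelled Tg, Mbnl1 stood at 4079, 2927, 3437 and 3509 CPM against 104, 96.9 and 97.1 in the day 7 controls, a log2 fold change of 5.13 ± 0.10. Among the controls, Mbnl1 rose from 72.3 ± 8.07 CPM at day 1 (SD, n = 4) to 99.3 ± 3.94 at day 7 (n = 3), and at day 60 it stood at 148 ± 2.80 (n = 4) and 160 ± 8.77 (n = 3). The log2 fold change of Mbnl1 was 0.45 ± 0.08 from day 1 to day 7 and 0.62 ± 0.08 from day 7 to day 60, and the latter was 0.02 and not called with total count scaling. The former was not called with all 27 libraries in a single fit or with replicate number as a block. From day 1 to day 60, Mbnl2 rose by 1.06 ± 0.08 on the log2 scale and Mbnl3 fell by 3.07 ± 0.36.

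**Figure D2:**
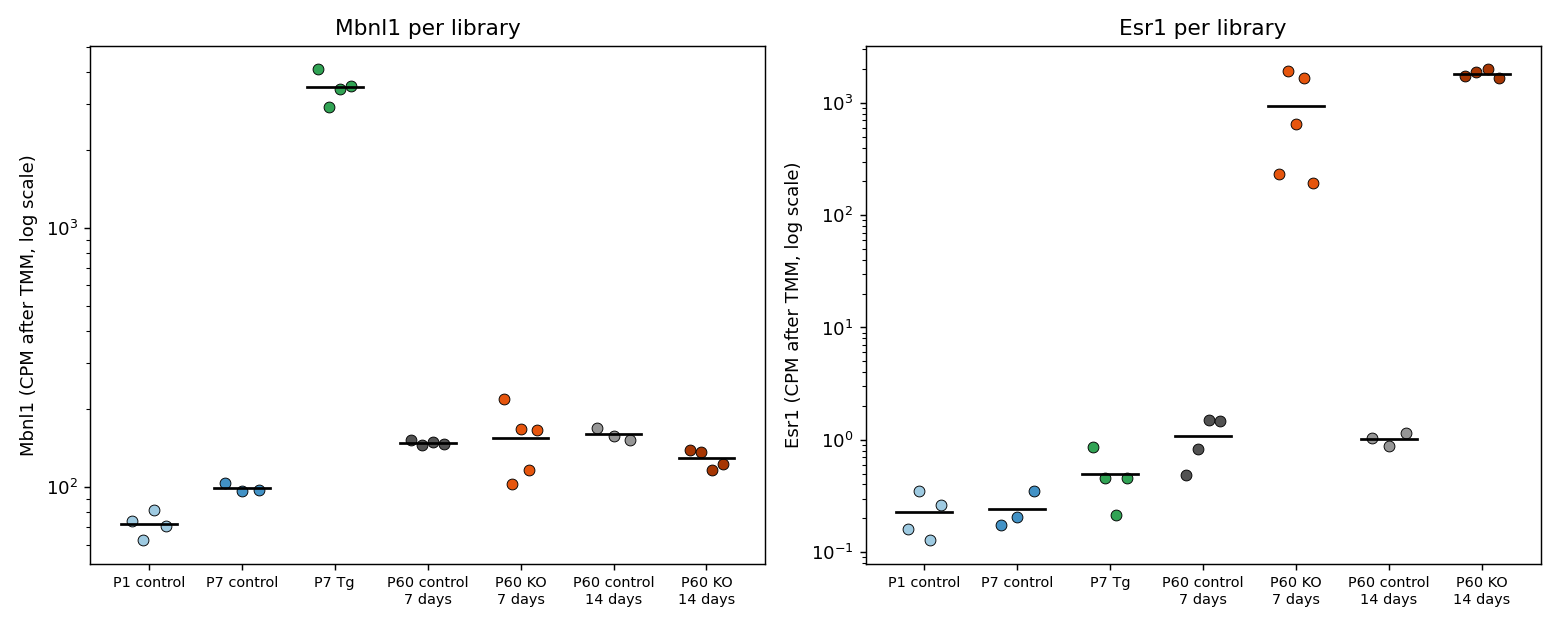
Levels of Mbnl1 and Esr1 in each of the 27 libraries (points, CPM on a log axis) by group, with the group mean as a line. Mbnl1 in the libraries labelled KO overlaps the controls at 7 days, Esr1 lies at 193 CPM or more in all 9 libraries labelled KO, and Mbnl1 lies at 2927 CPM or more in the 4 libraries labelled Tg.

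At 7 days after knockout, genes of the adult heart muscle cell and of its energy metabolism were lower in the libraries labelled KO (n = 5) than in their controls (n = 4). Of 30 adult cardiomyocyte genes, 26 fell and 1 rose, with the same counts adjusted over the list alone (median log2 fold change -1.31, camera adjusted p = 4.7e-10, and adjusted p = 0.27 with an estimated correlation). Kcnip2, a subunit of the channel for the transient outward potassium current, changed by -3.68 ± 0.63, Ppargc1a, a coactivator of genes for mitochondria, by -2.72 ± 0.50, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by -2.31 ± 0.15. The channel genes Kcnv2 and Cacna1s, with -4.75 ± 0.31 and -4.06 ± 0.23, were among the largest falls of genes with at least 5 CPM, as was Asb14 with -4.40 ± 0.41. Of 24 calcium handling genes, 14 fell and 3 rose, also adjusted over the list alone (median -0.75, camera adjusted p = 0.017, and adjusted p = 0.38 with an estimated correlation). These include Pln, which inhibits the calcium pump of the sarcoplasmic reticulum, with -2.30 ± 0.50, and the pump Atp2a2 itself with -1.92 ± 0.21.

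Of 32 fatty acid oxidation genes, 29 fell and 1 rose at 7 days, and 30 fell adjusted over the list alone (median -1.54, camera adjusted p = 2e-14, and adjusted p = 0.27 with an estimated correlation). Acot1 changed by -2.29 ± 0.38, the dehydrogenase Acadm by -1.97 ± 0.13 and the lipid droplet protein Plin5 by -1.93 ± 0.18. All 48 nuclear-encoded respiratory chain genes tested fell, also adjusted over the list alone (median -1.12, camera adjusted p = 2.3e-23, and adjusted p = 0.27 with an estimated correlation), as did all 21 citric acid cycle genes (median -1.22). Cox7a1, the muscle form of a cytochrome oxidase subunit, changed by -2.05 ± 0.18, and Idh2, the mitochondrial isocitrate dehydrogenase, by -1.63 ± 0.12. The citric acid cycle list had an adjusted p of 1.1e-12 by camera and an adjusted p = 0.27 with an estimated correlation. Of 13 mitochondrially encoded genes, 12 fell, also adjusted over the list alone (median -1.29, adjusted p = 0.33 with an estimated correlation). These genes held 16.6% ± 1.6 of the counts in the libraries labelled KO (SD, n = 5) and 27.8% ± 1.5 in the controls (n = 4, two-sided exact permutation p = 0.0159, 0.0571 after adjustment over 4 such comparisons).

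Fetal, proliferative and connective tissue genes were higher at 7 days in the libraries labelled KO. Of 21 fetal cardiac genes, 11 rose and 3 fell, and 12 rose and 4 fell adjusted over the list alone (median 0.87, camera adjusted p = 0.014, and adjusted p = 0.27 with an estimated correlation). Nppa, the atrial natriuretic peptide, stood at 1576 ± 1081 CPM against 86.7 ± 20.4, a log2 fold change of 4.16 ± 0.66, and Tnnt1, the slow skeletal troponin T, rose by 3.60 ± 0.23. Libraries 1 and 5 labelled KO held 576 and 248 CPM of Nppa against 2111 to 2535 in the other 3. They held 191 and 131 CPM of Myh7, looked at after its values were seen, against 226 to 317 in the controls and 1349 to 1722 in the other 3. Of 39 mitosis genes, 37 rose and 1 fell, also adjusted over the list alone (median 2.14, camera adjusted p = 9.5e-12, and adjusted p = 0.42 with an estimated correlation). Examples are Ccnb1 with 3.37 ± 0.40, Cdk1 with 2.98 ± 0.38 and Plk1 with 2.78 ± 0.31. DNA replication genes rose in 27 of 35 members and fell in 1, also adjusted over the list alone (median 1.07, adjusted p = 0.45 with an estimated correlation). Of 36 extracellular matrix genes, 30 rose and 0 fell, and of 19 genes of myofibroblast activation, 16 rose and 0 fell, with the same counts adjusted over the list alone (medians 2.06 and 3.20, adjusted p = 0.27 and 0.075 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, stood at 1877 CPM against 56.4, with a log2 fold change of 5.04 ± 0.37, Lox, which crosslinks collagen, rose by 5.25 ± 0.32 and Timp1, an inhibitor of matrix proteases, by 6.11 ± 0.71. Macrophage markers rose in 16 of 20 members and fell in 1, also adjusted over the list alone. Endothelial markers fell in 12 of 21 and rose in 0, or 13 and 0 adjusted over the list alone (medians 1.48 for macrophage and -0.43 for endothelial markers, adjusted p = 0.37 and 0.42 with an estimated correlation). Examples are Ccr2, a chemokine receptor of monocytes, with 4.57 ± 0.44, and Kdr, a receptor for vascular endothelial growth factor, with -0.91 ± 0.08.

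In all, 7693 of 15167 genes were called at 7 days, 4001 higher and 3692 lower, of which 3215 differed by at least 2-fold. With total count scaling 83.5% of the calls were higher, against 52.0% with TMM, and the median of all genes lay at 0.45 on the log2 scale against 0.03. Falls in expression given here are relative to the TMM scale, and the lists described here for 7 days kept the sign of their medians with total count scaling. That of the endothelial markers was then near 0, at -0.0087. Of the 22 lists called by camera at 7 days, 0 were called with an estimated correlation (smallest adjusted p 0.0748) and 33 lists moved on balance in a direction by fry.

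At 14 days after knockout, 25 of 30 adult cardiomyocyte genes fell and 1 rose in the libraries labelled KO (n = 4) against their controls (n = 3), also adjusted over the list alone (median -1.17, camera adjusted p = 1e-11, and adjusted p = 0.035 with an estimated correlation). Kcnip2 changed by -3.34 ± 0.19, Ppargc1a by -2.47 ± 0.31, Pln by -2.21 ± 0.10 and Ryr2, the calcium release channel of the sarcoplasmic reticulum, by -2.18 ± 0.19. Of the fatty acid oxidation genes, 29 of 32 fell and 0 rose, with Acot1 at -3.18 ± 0.20 and Acaa2, which carries out the final thiolysis step, at -2.12 ± 0.19 (median -1.58, camera adjusted p = 4.2e-19, and adjusted p = 0.089 with an estimated correlation). Again all 48 respiratory chain and all 21 citric acid cycle genes fell, with medians of -0.97 and -1.05 (adjusted p = 0.089 with an estimated correlation for both). These counts were the same adjusted over the list alone. Mitochondrially encoded genes fell in 10 of 13 members, also adjusted over the list alone (median -0.94, adjusted p = 0.24 with an estimated correlation). They held 19.4% ± 1.7 of the counts against 28.5% ± 1.8 (SD, n = 4 and 3, two-sided exact permutation p = 0.0571, the smallest that this test can give with these group sizes).

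Fetal cardiac genes rose in 13 of 21 members at 14 days and fell in 1, also adjusted over the list alone (median 1.14, camera adjusted p = 0.00011, and adjusted p = 0.065 with an estimated correlation). Nppa stood at 3799 ± 397 CPM against 99.3 ± 2.36, Tnni1, the slow skeletal troponin I of the fetal heart, rose by 4.32 ± 0.49 on the log2 scale and Acta1, skeletal actin, by 3.51 ± 0.31. Of the extracellular matrix genes, 34 of 36 rose and 0 fell, and 35 rose adjusted over the list alone (camera adjusted p = 6.9e-21, and adjusted p = 0.065 with an estimated correlation). Genes of myofibroblast activation rose in 17 of 19 members, with 17 higher and 1 lower adjusted over the list alone. Examples that rose are Cilp with 4.61 ± 0.22 and Ltbp2 with 4.58 ± 0.23. Macrophage markers rose in 13 of 20 and fell in 1, or 14 and 1 adjusted over the list alone (medians 2.89 for myofibroblast and 0.80 for macrophage genes, adjusted p = 0.065 and 0.34 with an estimated correlation). Of the endothelial markers, 7 of 21 fell and 2 rose, also adjusted over the list alone, and the list was not called (median -0.12, turning to 0.25 with total count scaling, camera adjusted p = 0.18). Mitosis genes rose in 11 of 39 members and fell in 1, or 8 and 1 adjusted over the list alone (median 1.35, camera adjusted p = 0.0053, and adjusted p = 0.71 with an estimated correlation), and the median was 0.88 without KO library 9. KO library 8 showed no such rise, with a mean log2 level of these genes of 0.459 against 0.385 to 1.24 in the controls, and Mki67 in it, looked at after its values were seen, stood at 3.38 CPM against 5.63 to 10.6. Without this library the median was 1.66. In all, 6623 of 14976 genes were called at 14 days, 3272 higher and 3351 lower, of which 2333 differed by at least 2-fold. The share of higher calls was 49.4%, and 81.9% with total count scaling, under which the median of all genes lay at 0.39.

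**Figure D3:**
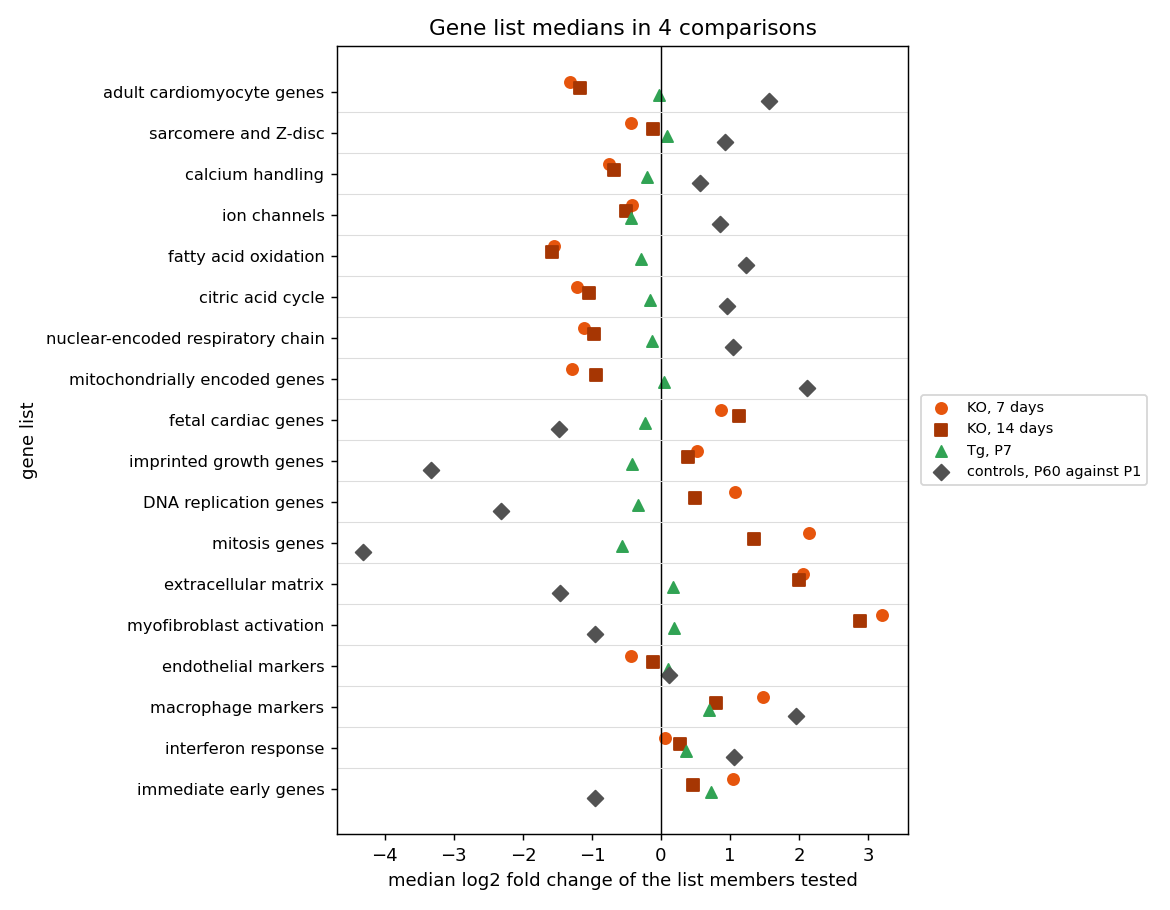
Median log2 fold change (horizontal axis) of 18 gene lists (vertical axis) in the libraries labelled KO at 7 and 14 days, in the libraries labelled Tg at day 7 and in day 60 against day 1 controls. Respiratory chain genes lie at -1.12 and -0.97 in KO and at 1.04 with age, and with total count scaling the sarcomere list turns from -0.43 to 0.00 at 7 days and from -0.11 to 0.26 at 14 days, the endothelial list from -0.12 to 0.25 at 14 days and from 0.11 to -0.55 with age, and the calcium handling list from 0.56 to -0.10 with age.

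Whether the response to knockout differed between 7 and 14 days was tested directly in the 16 libraries of day 60. Of 15951 genes, 0 were called by edgeR quasi-likelihood (smallest adjusted p 0.0693), 1662 had an unadjusted p under 0.05 where chance gives 798, limma-voom called 0 and DESeq2 147. Without KO library 2 of 7 days edgeR called 21. The difference in Mbnl1 was -0.36 ± 0.25 and that in Mbnl2 -0.28. A total of 21 lists was called by camera with the preset correlation, among them mitosis genes (median difference -0.74) and macrophage markers (-0.72), both lower relative to controls at 14 than at 7 days. The mitosis median was -0.43 and not called without KO library 8, -1.22 without KO library 9 and -0.40 without control library 7. With an estimated correlation 0 lists were called (smallest adjusted p 0.422) and fry called 0, so these calls rest on the preset correlation. Among the 14734 genes tested at both times, 2544 were higher at both and 2700 lower at both, where independent lists give 834 and 823. Of the genes called at both, 5244 of 5252 moved in the same direction (99.8%). The log2 fold changes correlated across genes with r = 0.884 and rho = 0.864, although genes are not independent replicates. Cthrc1, a secreted protein of activated fibroblasts, rose at both times, by 7.21 ± 0.93 and 5.87 ± 0.22. Tnnt3, the fast skeletal troponin T, stood at 45.7 ± 39.2 CPM against 0.331 at 7 days and at 41.8 ± 15.4 against 0.371 at 14 days. Sprr1a stood at 146 ± 72.4 CPM against 0.115 at 7 days and at 131 ± 58.4 against 0.220 at 14 days.

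At postnatal day 7, gain of MBNL1 was examined in 4 libraries labelled Tg against 3 controls. All 39 mitosis genes fell, also adjusted over the list alone (median -0.56, camera adjusted p = 7.9e-24, and adjusted p = 0.17 with an estimated correlation). Examples are the spindle genes Kif11 with -0.68 ± 0.10 and Cenpf with -0.67 ± 0.07. DNA replication genes fell in 25 of 35 members and rose in 1, or 26 and 1 adjusted over the list alone (median -0.33, camera adjusted p = 1.7e-09, and adjusted p = 0.049 with an estimated correlation). Tyms, the thymidylate synthase, changed by -0.55 ± 0.08. With all 27 libraries in a single fit, Kif11, Cenpf and Tyms were not called (adjusted p = 0.42, 0.27 and 0.33, edgeR quasi-likelihood). Of 22 p53 targets, 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.32, camera adjusted p = 5.4e-07, and adjusted p = 0.23 with an estimated correlation). Examples are Eda2r with 0.91 ± 0.11 and Phlda3 with 0.86 ± 0.08. Immediate early genes rose in 20 of 22 members, or 21 adjusted over the list alone (median 0.73, camera adjusted p = 2.4e-12, and adjusted p = 0.049 with an estimated correlation). These include Egr2 at 2.07 ± 0.28 and Btg2 at 1.70 ± 0.13.

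Ion channel genes fell in 17 of 29 members and rose in 1 in the libraries labelled Tg, or 19 and 1 adjusted over the list alone (median -0.43, camera adjusted p = 1.8e-06, and adjusted p = 0.092 with an estimated correlation). Hcn4, the pacemaker channel, changed by -1.74 ± 0.20, Cacna1g, a T-type calcium channel, by -1.38 ± 0.08 and Kcnj2, which carries the inward rectifier current, by -1.13 ± 0.10. Fatty acid oxidation genes fell in 22 of 32 members and rose in 3, or 23 and 5 adjusted over the list alone (median -0.29, camera adjusted p = 7.2e-07, and adjusted p = 0.23 with an estimated correlation). Respiratory chain genes fell in 20 of 48 and rose in 2, or 25 and 3 adjusted over the list alone, by small amounts (median -0.13, adjusted p = 0.33 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, changed by -0.29 ± 0.04. The mitochondrially encoded genes held 16.4% ± 0.35 of the counts against 15.5% ± 0.34 (SD, n = 4 and 3, two-sided exact permutation p = 0.0571, the smallest that this test can give with these group sizes). Macrophage markers rose in 14 of 19 members and fell in 1, also adjusted over the list alone (median 0.70, camera adjusted p = 1.9e-06, and adjusted p = 0.23 with an estimated correlation). Cd14, a receptor for bacterial lipopolysaccharide, rose by 1.23 ± 0.19. Markers of some other cell types were also higher in each library labelled Tg than in any control. Their mean log2 levels were 6.53 to 6.57 against 6.40 to 6.45 for endothelial markers. They were 5.65 to 5.84 against 5.56 to 5.61 for mural cell markers and 5.10 to 5.23 against 4.94 to 5.05 for fibroblast markers. They were -1.31 to -1.19 against -1.77 to -1.57 for lymphocyte and neutrophil markers. For epicardial markers they were 1.45 to 2.20 against 0.98 to 1.41, and for glial and neuronal markers 0.96 to 1.32 against 0.72 to 0.88. Those of erythroid and adipocyte markers overlapped between the groups. Sarcomere and Z-disc genes were higher too, at 9.55 to 9.68 against 9.35 to 9.41. Whether a lower share of heart muscle cells contributed to the falls in the libraries labelled Tg was not tested. Genes of the unfolded protein and heat shock response rose in 13 of 19, or 14 adjusted over the list alone (median 0.33, adjusted p = 0.23 with an estimated correlation). The chaperone Hspa5 rose by 0.70 ± 0.06.

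Among single genes in the libraries labelled Tg, Gdf15, a stress cytokine, stood at 18.3 CPM against 1.78 and rose by 3.35 ± 0.22 on the log2 scale, Nppb, the brain natriuretic peptide, stood at 262 against 51.2 and rose by 2.35 ± 0.10, and Xirp2, a protein of intercalated discs and myofibrils, stood at 447 against 80.2 and rose by 2.47 ± 0.17. Tmprss11d, a serine protease of airway epithelium (ENSMUSG00000061259, chromosome 5, 86302217 to 86373420 on the minus strand of GRCm38), stood at 1159 ± 84.0 CPM (SD, n = 4) against 0.0577 ± 0.0198 (n = 3). Whether this is a response to MBNL1 or an effect of the transgene construct or its site was not tested. Mbnl3 changed by -0.93 ± 0.24 and was not called without control library 1 or control library 3 (-0.79 for each, adjusted p = 0.053, edgeR quasi-likelihood), with all 27 libraries in a single fit or with replicate number as a block. Mbnl2 changed by -0.10 ± 0.05 (adjusted p = 0.15). Adult cardiomyocyte genes rose in 8 of 30 members and fell in 10, or 10 and 11 adjusted over the list alone, and the list was not called (median -0.03, camera adjusted p = 0.67). Fetal cardiac genes rose in 6 of 21 and fell in 8, also adjusted over the list alone (median -0.23, adjusted p = 0.58), and the signs of the list's median, mean and test differed. Splicing regulators rose in 4 of 30 and fell in 9, or 4 and 10 adjusted over the list alone (median -0.09, adjusted p = 0.15), again with signs that differed, and Rbfox1, a splicing factor of heart and brain, changed by -1.32 ± 0.12. In all, 4878 of 15893 genes were called, 2371 higher and 2507 lower, of which 535 differed by at least 2-fold, and 973 were called with all 27 libraries in a single fit.

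Normal postnatal change was described in the 14 control libraries. From day 1 to day 7, adult cardiomyocyte genes rose in 15 of 30 members and fell in 2, or 16 and 3 adjusted over the list alone (median 0.30, camera adjusted p = 0.00026, and adjusted p = 0.31 with an estimated correlation). Imprinted growth genes fell in 12 of 16, or 13 adjusted over the list alone (median -0.93, adjusted p = 0.16 with an estimated correlation). These include Dlk1 at -2.16 ± 0.23, H19 at -1.86 ± 0.17 and Igf2, the fetal growth factor, at -1.62 ± 0.26. Myh7, the slow myosin heavy chain of the fetal ventricle, stood at 263 CPM at day 7 against 5860 at day 1, a change of -4.48 ± 0.33. Glycolysis genes fell in 15 of 25 members and rose in 3, or 16 and 3 adjusted over the list alone (median -0.52, adjusted p = 0.39 with an estimated correlation). Their mean log2 level was 7.88 and 7.98 in day 1 libraries 1 and 2 but 7.31 and 7.49 in libraries 3 and 4. It was 7.00 to 7.10 in the day 7 controls, so most of the fall rests on the former pair. The glucose transporter Slc2a1 changed by -2.86 ± 0.44. Extracellular matrix genes rose in 22 of 36 and fell in 1, or 23 and 2 adjusted over the list alone. Fibroblast markers rose in 10 of 15 and fell in 1, also adjusted over the list alone (medians 0.51 for matrix and 0.86 for fibroblast genes, adjusted p = 0.31 and 0.067 with an estimated correlation). These include Lum with 1.43 ± 0.16 and Dcn with 1.38 ± 0.12. DNA replication genes were called in 0 of 35 members, also adjusted over the list alone (median -0.05, with signs of median, mean and test that differed), and the list was called with a rise without day 1 library 1 (0.18) or library 2 (0.15) and with a fall without day 1 library 3 (-0.36). In all, 3844 of 16388 genes were called, 2016 higher and 1828 lower. The count was 2536 without day 7 library 1 and 2508 without day 7 library 2. The share of higher calls was 52.4%, and 41.0% with total count scaling.

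From day 7 to day 60, all 39 mitosis genes and 34 of 35 DNA replication genes fell, also adjusted over the list alone (medians -3.89 and -2.21, adjusted p = 0.44 and 0.60 with an estimated correlation). Examples are Ccnb1 at -4.83 ± 0.23 and Rrm2, a subunit of ribonucleotide reductase, at -4.27 ± 0.43. All 48 respiratory chain and all 21 citric acid cycle genes rose, and 26 of 30 adult cardiomyocyte genes rose while 2 fell, also adjusted over the list alone (medians 0.89, 0.87 and 1.24, adjusted p = 0.24, 0.24 and 0.12 with an estimated correlation). Tcap, a titin-binding protein of the Z-disc, rose by 2.83 ± 0.19 and Slc2a4, the insulin-responsive glucose transporter, by 2.02 ± 0.09. Bdh1, a ketone body enzyme, stood at 0.429 ± 0.301 CPM at day 7, at 8.26 ± 3.35 at day 1 and at 123 ± 14.1 and 109 ± 21.2 in the day 60 groups. All 24 interferon response genes rose, also adjusted over the list alone (camera adjusted p = 2.2e-06, and adjusted p = 0.41 with an estimated correlation). Ifit3, an interferon-induced protein, rose by 4.37 ± 0.43. Extracellular matrix genes fell in 31 of 36 members and rose in 4, also adjusted over the list alone (median -1.91, adjusted p = 0.26 with an estimated correlation). Examples are Eln, elastin, at -4.20 ± 0.26 and Postn at -3.94 ± 0.15. Tnni1, the fetal troponin I, stood at 823 ± 72.4 CPM at day 7 and 1726 ± 223 at day 1, and at 0.489 and 0.796 in the day 60 groups. The latter mean was raised by library 7 of the 14-day controls, with 1.58 CPM against 0.306 and 0.499 in the others. In all, 11351 of 16388 genes were called, 5456 higher and 5895 lower, and 4827 differed by at least 2-fold. The share of higher calls was 48.1%, and 18.0% with total count scaling, under which the median of all genes lay at -0.65. That scaling called 8247 of the genes in the same direction and 1041 in the opposite direction.

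Over the whole span from day 1 to day 60, 12081 genes were called, 5753 higher and 6328 lower, and 5422 differed by at least 2-fold. The share of higher calls was 47.6%, and 19.3% with total count scaling, under which the median of all genes lay at -0.71. That scaling called 8993 of the genes in the same direction and 1336 in the opposite direction. Fatty acid oxidation genes rose in 25 of 32 members and fell in 2, also adjusted over the list alone (median 1.23, camera adjusted p = 1.2e-06, and adjusted p = 0.48 with an estimated correlation), and Lpl, lipoprotein lipase, rose by 2.70 ± 0.17. The mean log2 level of the fatty acid oxidation list was 6.02 and 6.12 in day 1 libraries 1 and 2 but 7.62 and 7.52 in libraries 3 and 4, against 7.92 to 8.40 in the day 60 controls, so most of the rise rests on the former pair. Mitochondrially encoded genes rose in 12 of 13, also adjusted over the list alone (median 2.11, adjusted p = 0.18 with an estimated correlation), and held 12.1% ± 1.3 of the counts at day 1 (SD, n = 4), against 27.8% and 28.5% in the day 60 groups. Fetal cardiac genes fell in 16 of 21 and rose in 2, also adjusted over the list alone (median -1.47, adjusted p = 0.18 with an estimated correlation). Macrophage markers rose in 18 of 20 and fell in 1, also adjusted over the list alone (median 1.96, adjusted p = 0.24 with an estimated correlation). These include Timd4 and Cd163, receptors of resident macrophages, with 5.01 ± 0.39 and 4.38 ± 0.49.

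The control groups of day 60, labelled with 14 and 7 days, were set against each other as a check of batch. The edgeR quasi-likelihood test called 5 genes, 2 higher and 3 lower. An unadjusted p under 0.05 was seen for 1113 genes where chance gives 819, DESeq2 called 70 and limma-voom 6. The higher genes, named after their values were seen, were Gm3375 and AC115117.1. Setdb2 stood at 8.95 CPM at 14 days against 18.1, a change of -1.04 ± 0.14, Wipf3 changed by -0.47 ± 0.07 and Zbp1 by -1.70 ± 0.25. The call of Setdb2 was lost without library 5, 6 or 7 and with all 27 libraries in a single fit, and that of Wipf3 without library 1, 3, 4, 5, 6 or 7 (-0.47, -0.45, -0.44, -0.49, -0.48 and -0.44). That of Zbp1 was lost without library 2, 4, 5, 6 or 7, and those of Wipf3 and Zbp1 with a sex covariate. Neither higher gene nor Wipf3 was called with all 27 libraries in a single fit. The count was 3 without library 4 and 2 without library 5 or 6. Ribosomal protein genes were called in 0 of 30 members and rose in 12 adjusted over the list alone (median 0.18, camera adjusted p = 3.9e-24, and adjusted p = 0.24 with an estimated correlation). Of the 6 lists called by camera, the medians that shifted further were those of interferon response genes, erythroid markers and glial and neuronal markers. Interferon response genes were lower in 1 of 24 members, or 12 adjusted over the list alone (median -0.63, camera adjusted p = 1.6e-21), and erythroid markers in 0 of 10, or 5 (median -0.98, camera adjusted p = 3.5e-07), both with an adjusted p of 0.26 with an estimated correlation. Glial and neuronal markers were called in 0 of 9 members, and 1 was higher adjusted over the list alone (median 0.57, and 0.33 and 0.35 without 14-day control library 5 or 6). This list was not called with an estimated correlation (adjusted p = 0.053), and by fry it alone was called (adjusted p = 0.0056).

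Maturation gene sets, defined as called and at least 2-fold different between day 60 and day 1 in control libraries outside each comparison, were then tested for their shift in the libraries labelled KO and in those labelled Tg. In the libraries labelled KO at 7 days, 1374 of 2368 genes higher at day 60 fell and 303 rose (median -0.73), while 1144 of 2004 genes higher at day 1 rose and 92 fell (median 0.71). Both shifts were called by camera, with adjusted p of 1.8e-18 and 6.8e-18, and with an estimated correlation (adjusted p = 0.0040 and 0.0015). At 14 days, 1230 of 2339 genes higher at day 60 fell and 326 rose (median -0.54), and 857 of 1948 genes higher at day 1 rose and 78 fell (median 0.57), both called with an estimated correlation (adjusted p = 0.019 and 0.038). In the libraries labelled Tg the shift had the opposite direction, with 694 of 2183 genes higher at day 60 that rose and 252 that fell (median 0.16), and 895 of 2546 genes higher at day 1 that fell and 150 that rose (median -0.20, adjusted p = 0.0011 for both with an estimated correlation). These directions held with total count scaling, and whether the shifts differ in size was not tested. The sets come from whole ventricle, so they do not describe heart muscle cells alone. In the libraries labelled Tg, mitosis and DNA replication genes fell and macrophage markers rose, as with age. Adult cardiomyocyte genes were not called as a list there. More fatty acid oxidation and respiratory chain genes fell than rose, although both lists rose with age.

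**Figure D4:**
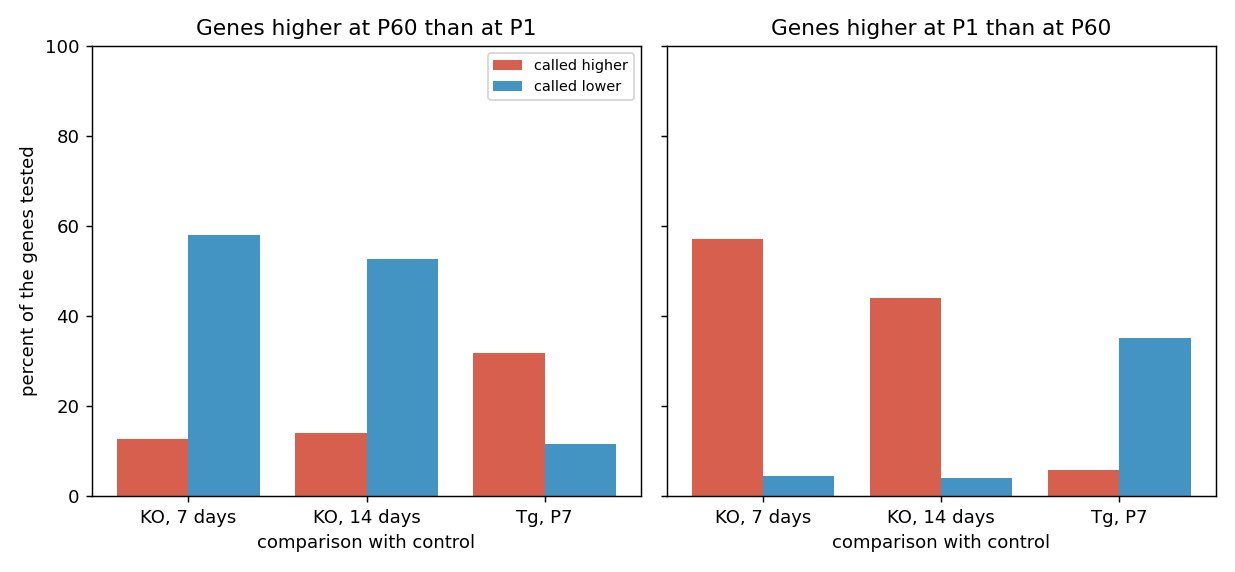
Percent of genes called higher and called lower (bars from 0, vertical axis) in the sets of genes higher at day 60 and of genes higher at day 1, for the libraries labelled KO at 7 and 14 days and those labelled Tg. Of genes higher at day 60, 58.0% were called lower in KO at 7 days and 31.8% were called higher in Tg.

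The changes in the libraries labelled KO and in those labelled Tg were compared gene by gene in fits that share no library. Of 2668 genes called both in KO at 7 days and in Tg, 1581 moved in the same direction (59.3%), with 768 higher in both and 813 lower in both, where independent lists give 585 and 584. Genes higher in KO and lower in Tg numbered 573 and those lower in KO and higher in Tg 514, where independent lists give 613 and 558, and the log2 fold changes correlated across genes with r = 0.150. For KO at 14 days and Tg, 1477 of 2357 genes moved in the same direction (62.7%, r = 0.142). Among genes that rose both in KO at 7 days and in Tg were Gdf15 and Nmrk2, a nicotinamide riboside kinase of muscle, with log2 fold changes of 2.73 ± 0.25 and 4.29 ± 0.53 in KO and of 3.35 ± 0.22 and 2.44 ± 0.16 in Tg. Cdnf, a neurotrophic factor of the endoplasmic reticulum that rose in Tg by 2.90 ± 0.08, changed by -2.14 ± 0.27 in KO at 7 days.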

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

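The tests of a swap or exchange of libraries, of the share of heart muscle cells, of the share of mitochondrially encoded counts, of Mbnl1 against Esr1, and of total count and sex for libraries 1 and 5 were chosen only after the result was seen, while the others were planned.

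Of 89 groups of per-library values examined, 5 held a library far from the rest of its group, and chance gives about 1 in 20. The 14-day controls and the day 7 controls, with 3 libraries each, were too small for this search and were left out of it. Mbnl3 stood at 0.482 CPM in library 1 of the 7-day controls against 0.119 to 0.166 in the others. These levels are 8 counts against 2 or 3 counts, and the latter lie at or below the floor of 3 counts. Postn stood at 395 CPM in day 1 library 3 against 632 to 669, and Tnni1 in the same library at 1395 against 1803 to 1868. Tmprss11d stood at 0.0391 CPM in KO library 5 of 7 days against 0 in the others. It stood at 0.0836 in KO library 8 of 14 days against 0.0423 to 0.0466, and all these values lay below the floor of 0.137. In the 14-day controls, looked at after the values were seen, Tmprss11d had 55 counts in library 7. Libraries 5 and 6 of that group had 1 and 4 counts. The count in library 7 lay above the floor of 3 counts, and its cause was not tested.

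By the test of the difference itself, with the preset correlation, 21 gene lists responded differently to knockout at 14 and at 7 days, given here as the median over the genes of a list of the log2 fold change at 14 days minus that at 7 days, which is not the difference between the medians of both times. Higher at 14 days were adult cardiomyocyte genes (0.31), respiratory chain genes (0.23), mitochondrially encoded genes (0.31), citric acid cycle genes (0.21), sarcomere and Z-disc genes (0.33), nuclear receptors of metabolism (0.27), fibroblast markers (0.31), endothelial markers (0.34), mural cell markers (0.021), erythroid markers (0.86), atrial markers (0.66) and interferon response genes (0.21). Lower were DNA replication genes (-0.48), mitosis genes (-0.74), extracellular matrix genes (-0.25), macrophage markers (-0.72), glial and neuronal markers (-0.54), unfolded protein and heat shock genes (-0.40), immediate early genes (-0.49), ribosomal proteins (-0.42) and microtubule genes (-0.55). With an estimated correlation and with fry 0 of these were called, and some calls with the preset correlation ended without a single library (KO 1 to 5 and control 1 to 4 are of 7 days, the rest of 14 days). The atrial median was then 0.52 and the erythroid one 0.66 (without control 7), that of the matrix -0.19 (KO 2), of microtubule genes -0.55 and of mitosis genes -0.43 (KO 8), and of glial markers -0.42 (KO 8) and -0.54 (control 5). The immediate early median was -0.32 (KO 1), -0.43 (KO 8), -0.26 (control 5) and -0.36 (control 6). The interferon median was 0.15 (KO 3 and control 4), 0.14 (KO 7 and control 6) and 0.11 (KO 9). The mural median was -0.03 (KO 2), -0.06 (KO 4) and 0.02 (control 5), and turned to -0.05 with total count scaling. It was also below 0, with the list still called higher, without control 1, KO 6 or KO 7.

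A first pattern was that Mbnl1 counts were not lower on average in the libraries labelled KO at 7 days while Esr1 counts were high in all of them. A swap of some KO libraries with controls is argued against, since no library was out of place on the second component, where the lowest of the 9 labelled KO lay at 30.3 and the highest of the 7 controls at -55.1. An exchange of all KO and control libraries cannot be told apart from correct labels by the Mbnl1 total. Mbnl1 changed by -0.34 at 14 days but not in that direction with total count scaling. Esr1 would decide it only if it marks the knockout animals, which is a hypothesis here. An exchange would give the controls the high Nppa of the libraries labelled KO, 248 to 4181 CPM against 63.4 to 113 in those labelled control. Whether unaltered day 60 ventricles hold such levels was not tested. RNA from a reproductive tissue that expresses Esr1 is argued against by 15 markers of such tissues, of which 11 stood under 1 CPM in the libraries labelled KO (median 0.0138 CPM, and 0.0129 in the day 60 controls). Some markers were higher, with Star at 49.9 CPM against 2.35, Krt8 at 6.70 against 0.114 and Muc1 at 1.71 against 0.491, and the reason for these was not tested. A deleted part too short to lower the gene total may account for the Mbnl1 level, as an internal exon of the longest transcript holds a median of 2.87% of its length, but the deleted part is not known here and the explanation cannot be told apart from the others. An Esr1 sequence within an inducible recombinase construct, carried by the animals labelled KO, also stays open as a hypothesis, since it is confounded with the genotype and was not tested.

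A second pattern was the fall of adult heart muscle and mitochondrial genes with the rise of matrix and macrophage genes in the libraries labelled KO. A lower share of heart muscle cells would raise the markers of every other cell type alike, and it is argued against as the whole cause at both times, since the markers moved apart. The mean log2 level of macrophage markers minus that of endothelial markers, which no scaling of a library changes, was higher in the libraries labelled KO by 2.04 at 7 days and by 0.89 at 14 days. The SD of this gap was 0.26 in KO and 0.11 in controls at 7 days and 0.16 and 0.084 at 14 days, with no overlap between the groups. A lower share together with more macrophages stays open. The lower share of mitochondrially encoded counts is argued against as the cause of the fall in adult heart muscle genes. With total count scaling it would raise all other genes by 0.21 on the log2 scale at 7 days, whereas the median of these genes was -0.89. A bias from GC content or transcript length is argued against as well, since 98.7% of the gap between the matrix and adult gene medians was kept after a correction that took up 0.92% of the variance of the log2 fold changes. A response to loss of MBNL1, more cells of other types, and effects of the construct carried by the animals labelled KO all stay open.

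A further pattern was that libraries 1 and 5 labelled KO at 7 days stood apart from the other 3. Total count is argued against, since both (2 of 2) lay within the range of the other 3, and so is a control library labelled KO, since their median change in the genes called at 14 days was 116% of that in the other 3. Both are the male libraries of their group, but sex by itself is argued against by the gap between the sexes on the fourth component in KO at 14 days, 6.51% of that at 7 days. A response to knockout at 7 days that may depend on sex stays open and was not tested. A weaker induction stays open too. Esr1 was lowest in these libraries, and over the 9 libraries labelled KO Mbnl1 was lower where Esr1 was higher (r = -0.877, exact permutation p = 0.0031 over both times together). Yet the change of 116% was not smaller than in the other 3. Adult cardiomyocyte genes were also lowest in libraries 1 and 5, with mean log2 levels of 7.83 and 7.55. The other 3 held 8.27 to 8.34 and the 7-day controls 9.5 to 9.6. Matrix genes in contrast lay nearer the controls, at 7.94 and 7.97 against 8.47 to 8.59 in the other 3 and 5.89 to 6.20 in controls. Low Esr1 by itself thus cannot be read as weaker induction. Leaving both libraries out gave 7964 called genes at 7 days.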

How the results depend on the processing

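Leaving out KO libraries 1 and 5 of 7 days, and day 1 libraries 3 and 4, were tests chosen only after the result was seen, and the others were planned. Depth limits what can be said of genes with 3 counts or fewer, 0.137 CPM before TMM scaling in the smallest library. The groups hold 3 to 5 libraries, and the sex and construct of the animals are not in the labels. The cause was not tested for any change given here, except where fewer libraries or a fold threshold by itself lowers a count.

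With a threshold of 2-fold added, the called genes numbered 3215 for KO at 7 days, 2333 for KO at 14 days, 535 for Tg, 1159 for day 7 against day 1, 4827 for day 60 against day 7 and 5422 for day 60 against day 1. For the difference between the times, 0 genes in the test as planned became 2 with total count scaling, 13 with no filter, 147 with DESeq2, 52 with all 27 libraries in a single fit, 2 with a term for sex, 3 without KO libraries 1 and 5, and 0 to 21 with each library left out in turn. For Tg, 973 genes were called with all 27 libraries in a single fit. For day 7 against day 1, 2508 to 4492 were called with each library left out and 5725 without day 1 libraries 3 and 4. For the day 60 controls, the 5 genes became 37 with no filter, 70 with DESeq2, 3 with all 27 libraries, 3 with a term for sex, 31 with 1 surrogate variable and 2 to 7 with each library left out. With each library left out, 6685 to 7610 genes were called for KO at 7 days, 5132 to 7256 for KO at 14 days, 3717 to 4486 for Tg, 10417 to 11468 for day 60 against day 7 and 11470 to 12202 for day 60 against day 1. Without day 1 libraries 3 and 4 the last count was 11979.

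Lists called with the preset correlation numbered 22 for KO at 7 days, 23 at 14 days, 21 for their difference, 23 for Tg, 21, 22 and 26 for the control ages and 6 for the day 60 controls. With an estimated correlation they numbered 0, 1, 0, 2, 0, 0, 0 and 0 in that order. For KO at 14 days, 15 lists were called with total count scaling, and fry called 0 for the difference between the times and 1 for the day 60 controls. With each library left out, 22 to 24 lists were called for KO at 7 days, 21 to 24 at 14 days, 17 to 23 for the difference, 21 to 26 for Tg, 20 to 21, 21 to 25 and 23 to 27 for the control ages, and 4 to 9 for the day 60 controls.

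Among the named genes and the lists, values that reversed were few. Over all genes, total count scaling called 1041 in the opposite direction from day 7 to day 60. This number was 1336 from day 1 to day 60 and 17 for KO at 7 days. With total count scaling Mbnl1 in KO at 14 days turned to 0.034, Rps15, Rpl37 and Rpl18 from day 7 to day 60 to -0.21, -0.36 and -0.36, the ribosomal proteins list of that comparison to -0.53, and Alas2 from day 1 to day 60 to -0.045. The value of mt-Co2, Tg against control, P7, ranged from -3.39 to 0.16 with each library left out, and turned to 0.16 without day 7 control library 2. Hba-a2 from day 7 to day 60 turned to 0.028 with the 7-day controls alone as day 60, and Angptl4 from day 1 to day 60 to 1.02 without day 1 libraries 3 and 4. In a further pair of lists the direction of the test reversed rather than the median. The DNA replication genes list from day 1 to day 7 (median -0.054) tested higher without being called, and was called lower without day 1 library 3 (-0.36) and without libraries 3 and 4 (-0.61), with medians of -0.36 to 0.18 over single libraries left out. The p53 targets list from day 1 to day 60 (median -0.017) tested lower by camera without being called, and was called higher by fry (adjusted p = 0.015). Over 984 results for single genes and 21249 values, 20434 kept their side of the threshold (10 of them with a changed sign), 797 lost the call, 10 gained it and 8 reversed. Over 328 list results and 5125 values the numbers were 4645 (205 with a median of changed sign), 313, 163 and 4.

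The medians of the maturation sets kept their direction and call with each library left out, from -0.77 to -0.69 and 0.68 to 0.76 for KO at 7 days, -0.58 to -0.52 and 0.52 to 0.67 at 14 days, and 0.15 to 0.17 and -0.21 to -0.19 for Tg.

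A block for the replicate number left 6589 called genes for KO at 7 days, 6163 at 14 days, 0 for the difference, 3830 for Tg, 1624 for day 7 against day 1, 10705 for day 60 against day 7 and 10092 for day 60 against day 1. These fits kept only libraries whose number occurs in both groups. That left 4 libraries per group at 7 days, 2 at 14 days and 3 for Tg. The age comparisons with day 60 used the 7-day controls alone. Lost calls in these fits thus cannot be credited to the block by itself. Libraries that share a number correlated with r from -0.207 to 0.0818, not every library correlated best with its own number, and the numbers thus give no pairing. The check of the day 60 controls has no block, because those groups share fewer than 2 numbers.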

Other observations

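The tests in this part, the other splits of the samples, were planned, and none was chosen only after the result was seen.

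In the libraries labelled KO, further gene lists changed beside those described so far. At 7 days, immediate early genes rose in 15 of 22 members and fell in 3, also adjusted over the list alone (median 1.04, adjusted p = 0.43 with an estimated correlation). These include the transcription factors Egr2 at 4.64 ± 0.34 and Egr1 at 2.13 ± 0.26. Genes of the integrated stress response rose in 12 of 21 and fell in 2, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.45 with an estimated correlation). Phgdh, an enzyme of serine synthesis, rose by 2.28 ± 0.27. Nuclear receptors of metabolism fell in 14 of 21 and rose in 2, or 16 and 2 adjusted over the list alone (median -0.83, adjusted p = 0.27 with an estimated correlation). Rxrg, a retinoid receptor, changed by -1.91 ± 0.45, whereas Dio2 and Dio3, which activate and inactivate thyroid hormone, rose by 2.67 ± 0.32 and 5.08 ± 0.98. Ribosomal proteins rose in 14 of 30, or 18 adjusted over the list alone (median 0.42, adjusted p = 0.54 with an estimated correlation). Their mean log2 level was 8.06, 8.01 and 8.09 in KO libraries 1, 3 and 5 but 7.51 and 7.45 in libraries 2 and 4, near the 7.31 to 7.47 of the controls. The YAP and TEAD targets Ankrd1 and Ccn2 rose by 2.61 ± 0.19 and 2.41 ± 0.24 at 7 days and by 2.76 ± 0.16 and 2.74 ± 0.16 at 14 days, and Dio2 by 4.33 ± 0.23 at 14 days.

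In the libraries labelled Tg, imprinted growth genes fell in 11 of 16 members, or 12 adjusted over the list alone (median -0.42, adjusted p = 0.21 with an estimated correlation). Mest changed by -0.82 ± 0.05. Cardiac transcription factors fell in 9 of 20 and rose in 0, also adjusted over the list alone (median -0.14, adjusted p = 0.26 with an estimated correlation). These include Hand1 at -1.48 ± 0.31 and Hey2 at -1.34 ± 0.07, and genes of the integrated stress response rose in 12 of 21, or 13 with 1 lower adjusted over the list alone (median 0.31, adjusted p = 0.23 with an estimated correlation). Chac1, an enzyme of glutathione breakdown, rose by 2.38 ± 0.15. Among the controls, epicardial markers fell in all 11 members from day 1 to day 60, also adjusted over the list alone (median -3.78, adjusted p = 0.21 with an estimated correlation), and circadian clock genes rose in 13 of 18 and fell in 2, also adjusted over the list alone (median 0.99, adjusted p = 0.24 with an estimated correlation). Interferon response genes fell in 12 of 24 from day 1 to day 7, or 13 adjusted over the list alone (median -0.94, adjusted p = 0.61 with an estimated correlation), and rose in all 24 from day 7 to day 60. The fall was absent in day 1 library 3. Its mean log2 level of these genes was 1.06, against 0.95 to 1.28 at day 7 and 1.71 to 2.41 in the other day 1 libraries.

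Other splits of the same libraries into groups of the same sizes were used to ask whether the counts of called genes exceed chance, with up to 40 splits drawn. No other split reached the number of genes called in KO at 7 days (7693, highest other split 2493), KO at 14 days (6623 and 1712), Tg (4878 and 10), day 7 against day 1 (3844 and 2336), day 60 against day 7 (11351 and 1) and day 60 against day 1 (12081 and 1), each matched by 1 split, the real one. This argues against chance but does not exclude it. The smallest share that 35 or 40 splits can give is 1 of 35 or 1 of 40. The shares were not adjusted for the number of such tests. For the day 60 controls the count was matched by other splits (5 called, highest other 7, matched by 4 of 35). For the difference between the times the splits decide nothing, since 0 genes were called and all 40 of 40 splits reach that count by necessity, and the highest other split called 290. That split points to a structure of the samples whose cause was not tested. It left all 9 libraries labelled KO at their own time and exchanged the time of 6 of the 7 controls. No other split reached the gap between the medians of the maturation sets in KO at 7 days (1.44, highest other 1.12), KO at 14 days (1.10 and 0.863) and Tg (0.353 and 0.277), with the same limit.

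For the number of gene lists called with the preset correlation, chance cannot be excluded in KO at 7 days (22, highest other 22, matched by 2 of 40 splits), KO at 14 days (23 and 25, 4 of 35), Tg (23 and 24, 3 of 35), day 7 against day 1 (21 and 24, 4 of 35), day 60 against day 7 (22 and 23, 6 of 40) and the day 60 controls (6 and 14, 25 of 35). For the difference between the times (21 and 19) and for day 60 against day 1 (26 and 24), 1 of 40 splits, the real one, gave as many, but neither count is secure. The former was 17 without KO library 8, 18 without 14-day control library 5 and 19 without 14-day control library 6, and 0 with an estimated correlation. The latter was 23 without 14-day control library 7, day 1 library 1 or day 1 library 2, 21 with total count scaling and 0 with an estimated correlation.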
